A study of Cicer arietinum with 20 samples.

How the data were processed

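Chickpea seedlings were sprayed with spores of the fungus Ascochyta rabiei, the agent of Ascochyta blight, or with water, and RNA of stem and leaf was compared on 2-colour spotted arrays. The 20 columns analysed here cover 4 genotypes (FLIP94-508C, ICC3996, ILWC245 and Lasseter) at 5 times (6, 12, 24, 48 and 72 hours after inoculation), with 1 column for each genotype and hour. Genotype and hour were taken from the sample titles. Per the labels, each column is the authors' mean over 3 biological replicates with dye swaps between control and inoculated RNA. The series' design text adds 6 technical replicates, giving 18 data points behind a column. These data points were not used here, so a column carries no replicate spread of its own.

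The deposited values are log2 ratios. Per the labels' design text, the authors subtracted the local background from each spot, left out spots marked as poor, applied Lowess normalisation over the whole population, formed the ratio of mean signals, took a shifted log of base 2 and combined duplicate spots. They used ImaGene for spot quantification and GeneSight for the transformations, per the same text. A shift added before the log pulls the ratios of dim spots towards 0, and its size is not given in the sources used here. Column medians lay between -0.01 and 0.01, so the columns were already centred. The direction of the ratio is likely inoculated over water control, because channel 1 is labelled control, channel 2 treatment, and the design text speaks of changes against the untreated control. It is not stated outright, and every "higher" and "lower" rests on that reading. The values ranged from -1.93 to 1.92, and the base of the log was taken from the design text. The number of arrays limits the precision, and signal intensities were not analysed here.

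The value table has 768 spots, of which 12 are controls. Of the other 756 probes, 711 had a value in at least 1 column and 481 had a value in all 20. The table lists probes by ID alone, and 0 IDs matched the RefSeq gene table used here, so the sources used here do not pair the IDs with genes. The gene lists, tissue marker lists and the averaging of probes of one name that had been fixed beforehand could therefore not be run. Probe IDs are given for at most 2 probes in each direction of a comparison.

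Probes at least 1.8-fold higher or lower, the size named in the design text, were counted in each column and over the 5 hours of each genotype, without a test. Overlaps between genotypes were tested with the two-sided Fisher's exact test over probes measured in both genotypes, with Benjamini-Hochberg adjustment over 12 tests. Neighbouring and related probes are not independent replicates. After the counts had been seen, the percent of measured probes at 1.8-fold was tested by exact permutation of hours within genotype (1728000 arrangements) and of genotypes within hour (331776 arrangements), adjusted over both tests.

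For tests of single probes, limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes) on the log2 ratios, with genotype and hour as additive terms. The genotype term gives the mean response over the 5 hours, which was tested against 0. On the same model, each genotype was compared with Lasseter, any difference among genotypes and among hours was tested with moderated F tests, and the mean of 24, 48 and 72 hours was compared with that of 6 and 12 hours. The threshold was an adjusted p of 0.05 (Benjamini-Hochberg). Probes entered with values in at least 3 of the 5 hours of every genotype (587 probes), of which 7 had an hour with no value in any genotype, leaving 580. The hours of a genotype are not replicates. The spread in this model is the deviation of a genotype from the shared time course, so a response that comes at 1 hour in 1 genotype counts as error, and the p-values say nothing of the spread between plants. The median residual SD was 0.16 on the log2 scale.

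The model was tested on simulated data for the same 580 probes. For the mean response of ICC3996 it recovered 90% of probes changed by 0.4 on the log2 scale and 98% of those changed by 0.85. For ICC3996 minus Lasseter it recovered 71% and 95% at these sizes, for any difference among genotypes 72% and 95%, for late minus early 82% and 99%, and for any difference among hours 78% and 97%. The simulated changes were constant over the hours or genotypes concerned. At each size 100 probes were changed together, which eases the Benjamini-Hochberg threshold, and the noise was drawn independently for each value. From 167 to 190 probes were called, against 7 in the real data for the mean of ICC3996 and 0 for the other comparisons simulated. The shares recovered are therefore not the power to find a few changed probes in the real data.

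Named probes passed the threshold with the same sign at all 5 hours (for late minus early, in all 4 genotypes), and the largest in each direction were taken. Where none passed, the 3 with the smallest p are given as values. These rules and the other settings were fixed before the data were examined. The settings were centring of columns, quantile normalization, probes complete in all columns, robust eBayes, no hour term, each column and each hour left out, fold sizes of 1.5 and 2, and a test over the hours of a genotype, called the methods' t-test because the design text names a t-test. That text describes it over replicate data points, which were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.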

Results

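The data describe how the shoots of 14-day-old chickpea seedlings changed gene expression after inoculation with Ascochyta rabiei, a fungus that causes blight lesions on leaves and stems. Lasseter is known as a susceptible cultivar, ICC3996 as a resistant accession, FLIP94-508C as moderately resistant and ILWC245 as a resistant accession of the wild relative Cicer echinospermum; this is background, since the labels used here give no resistance class and name Cicer arietinum as the organism of all 20 columns. Each genotype was measured at 5 hours against water-sprayed plants of the same genotype, and each of the 20 columns is the authors' mean log2 ratio over 3 biological replicates. Between 555 and 702 probes had a value in a column. There is no spread between replicates for a single column, so counts and values of single columns are given without an error.

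The first question was how many probes reached 1.8-fold in each genotype at each hour. Few probes moved far. Over the 20 columns, 193 values reached 1.8-fold, of which 98 were higher and 95 lower after inoculation, and of the 711 measured probes 56 were higher and 61 lower in at least 1 column, with 9 probes in both sets. ICC3996 had 13 such probes at 6 hours (10 higher and 3 lower), when Lasseter had 3 and FLIP94-508C had 3, all those of Lasseter being lower. ILWC245 had 10 at 6 hours, of which 8 were lower. At 12 hours the counts were 8 in ICC3996, 5 in Lasseter, 1 in ILWC245 and 0 in FLIP94-508C. At 24 hours they were 17 in ICC3996, 17 in FLIP94-508C, 19 in Lasseter and 11 in ILWC245. At 48 hours FLIP94-508C had 18, Lasseter 16, ICC3996 15 and ILWC245 4. At 72 hours the count was 14 in ICC3996, against 8 in FLIP94-508C, 6 in ILWC245 and 5 in Lasseter. In Lasseter no probe was 1.8-fold higher at 6 or 12 hours, and 9 and 12 were at 24 and 48 hours. Such a count rises with the spread of all probes in a column, whatever its source. That spread (median absolute deviation of the log2 ratio) ran from 0.13 in Lasseter at 12 hours to 0.27 in FLIP94-508C at 48 hours. These columns had 5 and 18 probes at 1.8-fold, while ICC3996 at 24 hours had 17 at a spread of 0.16. The counts were not adjusted for spread, so they do not measure the strength of a response alone.

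**Figure D1:**
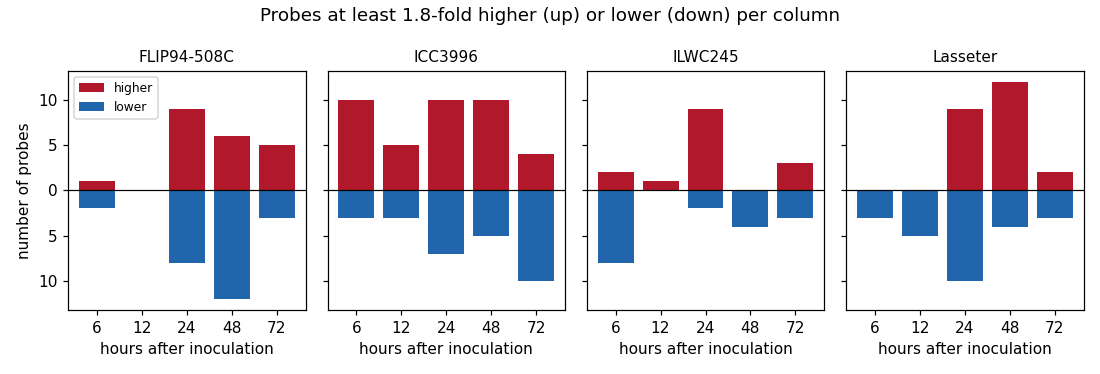
Number of probes at least 1.8-fold higher (red, upwards) or lower (blue, downwards) after inoculation, on the vertical axis, against hours after inoculation, in 4 panels for the 4 genotypes. Each bar is 1 column, a mean over 3 biological replicates, so there is no error bar; ICC3996 has 10 higher probes at 6 hours and Lasseter has 0.

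As a share of measured probes, those at 1.8-fold averaged 1.23% ± 0.865 at 6 hours, 0.502% ± 0.528 at 12 hours, 2.61% ± 0.589 at 24 hours, 2.30% ± 1.08 at 48 hours and 1.35% ± 0.643 at 72 hours (mean ± SD over n = 4 genotypes). The hours differed in this share (exact permutation of hours within genotype, p = 0.00548, adjusted p = 0.0110), a test chosen after the counts had been seen. It lost its call when the 12-hour columns (exact p = 0.0556), the 24-hour columns (exact p = 0.0584) or FLIP94-508C (exact p = 0.0639) were left out. Quantile normalization leaves 8 or 9 probes at 1.8-fold in every column by construction, so the hours then differ in share through the number of measured probes alone. By genotype the share averaged 2.20% ± 0.634 in ICC3996, 1.59% ± 1.26 in Lasseter, 1.54% ± 1.37 in FLIP94-508C and 1.07% ± 0.679 in ILWC245 (SD over n = 5 hours). These did not pass the test (exact permutation of genotypes within hour, p = 0.133), although at 2-fold the exact p was 0.0467. The 12-hour columns stood apart in another way: 674 to 702 probes had a value in them, against 555 to 629 at the other hours.

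The second question was whether the genotypes responded through the same probes. Over the 5 hours, 51 probes reached 1.8-fold in ICC3996 (31 higher, 22 lower), 42 in Lasseter (18 higher, 24 lower), 41 in FLIP94-508C (19 higher, 23 lower) and 30 in ILWC245 (14 higher, 16 lower); a probe can be in both directions at different hours. The order of the genotypes changed under quantile normalization, which gives all columns 1 distribution: the counts were then 34 in ICC3996 and 40 in each of the others. Most were seen in 1 genotype: 43 of the 56 higher probes and 44 of the 61 lower ones. The sets still overlapped more than independent sets of their size. FLIP94-508C and ILWC245 shared 8 higher probes against 0.392 by chance, ILWC245 and Lasseter shared 7 against 0.349, and FLIP94-508C and ICC3996 shared 9 against 0.844 and 10 lower probes against 0.725. All 12 overlaps passed Fisher's exact test, with adjusted p from 1.0e-09 to 0.0110. The weakest were the 3 overlaps of lower probes with ILWC245, each of 3 probes. Every overlap of higher probes holds the same 6 probes, those higher in all 4 genotypes. For FLIP94-508C with Lasseter these 6 are the whole overlap. The overlaps of higher probes are therefore not separate evidence of broad sharing. Fisher's test also gives every measured probe the same chance of reaching 1.8-fold. Probes that vary widely in every genotype would overlap without a shared response, so the overlaps alone cannot decide whether the genotypes responded through the same probes. Few probes reached 1.8-fold at 2 or more hours in one direction: 9 in ICC3996, 5 in Lasseter, 3 in FLIP94-508C and 2 in ILWC245.

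A common set of 6 probes was at least 1.8-fold higher in every genotype, and no probe was lower in all 4. The set had its highest values at different hours. In ICC3996 the median log2 ratio over the 6 probes was 1.30 at 12 hours, 1.08 at 24 hours, 0.84 at 48 hours and 0.34 at 72 hours. In FLIP94-508C it was 0.57 at 12 hours, 1.10 at 24 hours and -0.11 at 72 hours. In ILWC245 it was 0.67 at 6 hours, 0.41 at 12 hours, 1.53 at 24 hours, -0.30 at 48 hours over 3 measured probes and 1.08 at 72 hours over 2. In Lasseter it was -0.20 at 12 hours, 0.90 at 24 hours over 5 measured probes, 1.31 at 48 hours and 0.70 at 72 hours. The highest value fell at 12 hours for 4 of the 6 probes in ICC3996, at 24 hours for 6 of 6 in FLIP94-508C and 5 of 6 in ILWC245, and at 48 hours for 5 of 6 in Lasseter. At 6 hours 2 of the 6 probes were measured in ICC3996 and in Lasseter, and at 48 and 72 hours 3 and 2 were measured in ILWC245.

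At 12 hours all 6 probes were higher in ICC3996 than in Lasseter, by a median of 1.37 on the log2 scale (range 0.35 to 2.04), while at 48 hours 0 of the 6 were, with a median difference of -0.50 (range -0.99 to -0.05). For FLIP94-508C against Lasseter the median difference was 0.70 at 12 hours, with 5 of 6 probes higher, and -0.78 at 48 hours, with 0 of 6 higher. The columns have no replicate spread here, so these differences were not tested. Under quantile normalization the median difference of ICC3996 minus Lasseter was 1.19 at 12 hours and -0.28 at 48 hours. The 48-hour column of Lasseter had a wider spread over all probes than that of ICC3996 (median absolute deviation 0.22 against 0.17). Probe LS0688 stood at 3.36-fold in ICC3996 at 12 hours, when it was 0.826-fold in Lasseter, and reached 2.80-fold in Lasseter at 48 hours. Probe U271 stood at 2.11-fold in ICC3996 at 12 hours and at 3.49-fold in Lasseter at 48 hours. The set and these 2 probes were chosen after their values were seen. Membership needed 1.8-fold in Lasseter at some hour. All 6 probes reached it there at 48 hours, and LS0688 and LS0759 at no other hour. High values of Lasseter at 48 hours, and the negative differences at that hour, thus follow in part from the choice of the set. With the 24-hour columns left out, 0 probes were 1.8-fold higher in all 4 genotypes.

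**Figure D2:**
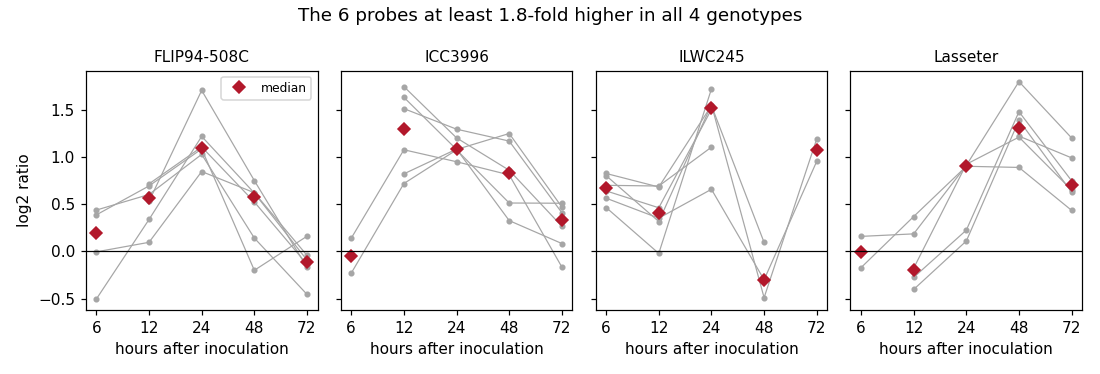
Log2 ratio on the vertical axis against hours after inoculation for the 6 probes that were at least 1.8-fold higher in every genotype, in 4 panels for the 4 genotypes. Each grey line is 1 probe, broken where a value is missing, and each red diamond is the median of the measured probes; the highest median is at 12 hours in ICC3996 (1.30) and at 48 hours in Lasseter (1.31).

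The most extreme single values were 3.78-fold higher for probe LS0660 in ICC3996 at 6 hours and 3.75-fold higher for LS0105 in FLIP94-508C at 24 hours, and 3.80-fold lower for LS0709 in Lasseter at 6 hours and 3.53-fold lower for LS0993 in Lasseter at 12 hours. These are single columns without a test.

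The third question was which probes responded in a genotype over the whole course. Probe U133 was below 0 in 19 of the 19 columns that measured it, and it passed the limma test in all 4 genotypes. It fell by 0.67 ± 0.08 (SE) on the log2 scale in FLIP94-508C (adjusted p = 0.000614, 5 of 5 hours), by 0.56 ± 0.08 in ICC3996 (adjusted p = 0.00211, 5 of 5 hours), by 0.55 ± 0.09 in ILWC245 (adjusted p = 0.0241, 4 of 4 measured hours) and by 0.39 ± 0.08 in Lasseter (adjusted p = 0.0352, 5 of 5 hours). In ILWC245 and Lasseter this call was lost under quantile normalization and when some single columns were left out (every one of its own in Lasseter), with adjusted p over the alternatives from 0.0163 to 0.194 and from 0.0199 to 0.102. In FLIP94-508C and ICC3996 it passed under all 29 alternative limma settings. The alternatives counted here leave out the methods' t-test, which after adjustment called 2 probes in FLIP94-508C and 1 in ICC3996.

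Of 580 probes, 13 passed in Lasseter (6 higher, 7 lower), 8 in FLIP94-508C (1 higher, 7 lower), 7 in ICC3996 (1 higher, 6 lower) and 1, U133, in ILWC245. In FLIP94-508C probe U187 fell by 0.68 ± 0.15 (adjusted p = 0.0287, 5 of 5 hours). In ICC3996 probe U461 fell by 0.81 ± 0.11 (limma, adjusted p = 0.00146, 5 of 5 hours) and passed under all 30 alternative limma settings. The methods' t-test called 1 probe in ICC3996 after adjustment, so U461 and U133 cannot both pass it there. Probe CA1198 rose by 0.40 ± 0.08 in ICC3996 (limma, adjusted p = 0.0305, 5 of 5 hours). In Lasseter probe LS0185 rose by 0.62 ± 0.13 (adjusted p = 0.0352), U017 rose by 0.39 ± 0.07 (adjusted p = 0.0143) and U153 fell by 0.27 ± 0.07 (adjusted p = 0.0497), each at 5 of 5 hours. For ILWC245 the next smallest p belonged to U349, at 0.19 ± 0.04 (adjusted p = 0.106), and U270, at 0.15 ± 0.04 (adjusted p = 0.110). Of the probes called, 19 were called in 1 genotype, 3 in 2 genotypes and 1 in all 4; whether a response differed between genotypes is tested separately. None of the 6 common probes passed in any genotype (smallest adjusted p = 0.0889, in Lasseter).

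The calls of U187, CA1198, LS0185, U017 and U153 were lost when some single columns were left out, with adjusted p up to 0.158, 0.149, 0.169, 0.0930 and 0.154. Without its 6-hour column FLIP94-508C had 1 call and without its 72-hour column 21, and Lasseter had 0 without its 6-hour, 48-hour or 72-hour column, 26 without the 24-hour column of FLIP94-508C and 27 among the 481 probes measured in every column. After centring on column medians the calls in Lasseter were 6 higher and 4 lower, and after quantile normalization they were 0 higher and 5 lower in FLIP94-508C and 2 higher and 6 lower in ICC3996.

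The fourth question was whether the response of each genotype differed from that of Lasseter. Probe CA0853 was higher in ILWC245 than in Lasseter by 0.30 ± 0.05 on the log2 scale (limma, adjusted p = 0.0477), with the same sign at 5 of 5 hours. Its mean ratio was 0.16 ± 0.07 in ILWC245 and -0.14 ± 0.11 in Lasseter (SD, n = 5 hours), and both are far from 1.8-fold. It was the single probe of 580 to pass in this comparison, where 81 had an unadjusted p under 0.05 and 29 would by chance. The call was lost with robust eBayes (adjusted p = 0.0548) and with any column of ILWC245, Lasseter or ICC3996 left out (limma, adjusted p from 0.0585 to 0.187). Over all 30 alternative limma settings the adjusted p ran from 0.0225 to 0.342, with 8 under 0.05. By the methods' t-test 0 probes passed in this comparison after adjustment.

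**Figure D3:**
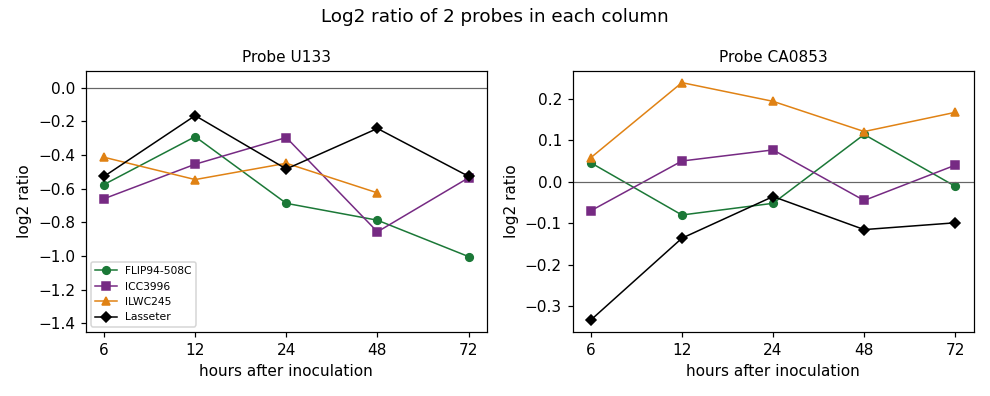
Log2 ratio on the vertical axis against hours after inoculation for probe U133 (left) and probe CA0853 (right), with 1 line and marker for each genotype and 1 point for each column, without error bars. U133 is below 0 in all 19 measured columns, and CA0853 is above 0 at 5 hours in ILWC245 and below 0 at 5 hours in Lasseter.

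For ICC3996 minus Lasseter 0 probes passed (limma; 39 at an unadjusted p under 0.05; 55 by the methods' t-test without adjustment and 0 with it). The smallest p belonged to U111, at 0.68 ± 0.20, U072, at -0.44 ± 0.11, and U404, at -0.22 ± 0.06, all with an adjusted p of 0.623. For FLIP94-508C minus Lasseter 0 passed (33 at an unadjusted p under 0.05; 20 by the methods' t-test without adjustment and 0 with it). The smallest p belonged to CA0810, at 0.51 ± 0.14, LS0493, at 0.44 ± 0.13, and U188, at -0.18 ± 0.06, all with an adjusted p of 0.705. The test of any difference among the 4 genotypes called 0 probes (limma F test, 41 at an unadjusted p under 0.05, smallest adjusted p = 0.478). In each of these comparisons, too, 29 would have an unadjusted p under 0.05 by chance. Probes are not independent, and no count of unadjusted p, that of ILWC245 minus Lasseter included, was set against regrouped columns. An excess over 29 was thus not tested. A difference that holds at 1 hour and turns at another, as in the common probes, averages out in these comparisons.

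The fifth question was whether probes changed between early and late hours in all genotypes alike. No probe passed for the mean of 24 to 72 hours minus that of 6 and 12 hours (limma, 66 at an unadjusted p under 0.05 against 29 by chance). Probe U222 came nearest, at 0.47 ± 0.09 (adjusted p = 0.0557, positive in 4 of 4 genotypes), followed by LS0156, at 0.43 ± 0.08 (adjusted p = 0.115), and U024, at -0.29 ± 0.07 (adjusted p = 0.190). The test of any difference among hours called 0 probes (73 at an unadjusted p under 0.05, smallest adjusted p = 0.146). Leaving out the 24-hour column of FLIP94-508C gave 8 calls among hours and 4 for late minus early, and leaving out all 24-hour columns gave 5 for late minus early.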

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

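The tests of the 12-hour columns, of exchanged columns and of column spread in this part were chosen after the results had been seen; the correlation among the common probes and the regroupings of columns were set out before they were run, the exchanges within hours after the first splits had been seen. Of 85 groups of 4 or 5 columns examined for a value far from the others, 5 were past the limit, and chance puts about 1 in 20 past it.

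Of the 6 probes that were 1.8-fold higher in every genotype, 4 had their highest value at 12 hours in ICC3996 and 5 at 48 hours in Lasseter. The spread (median absolute deviation) of the 12-hour column was 0.17 in ICC3996 and 0.13 in Lasseter. In units of each column's own spread, ICC3996 stood above Lasseter by a median of 8.24 ± 4.47 (SD over the 6 probes). This cannot decide whether a wider spread of the ICC3996 column plays a part. The 6 probes were chosen for reaching 1.8-fold, which lies far outside either spread. An exchange of the 12-hour and 24-hour columns in ICC3996 was argued against by the number of measured probes. The ICC3996 column labelled 12 hours had 698, against 674 to 702 in the other 12-hour columns and 606 to 629 in the other 24-hour columns. So was an exchange of the 24-hour and 48-hour columns in Lasseter. The Lasseter column labelled 48 hours had 562, against 555 to 584 in the other 48-hour columns and 606 to 629 in the other 24-hour columns. Other exchanges were not examined, and the number overlaps between 6 hours (585 to 607), 24 hours (606 to 629) and 72 hours (580 to 620). It stays open whether the 6 probes may read 1 transcript or family, since their median pairwise correlation over the columns was 0.717 (range 0.579 to 0.932), which does not decide it. Of the 15 pairs, 3 reached a correlation of 0.9 or more. Some of the 6 may thus read the same transcript, and the counts of 4 and 5 probes may rest on fewer transcripts. An earlier response in ICC3996 than in Lasseter is a hypothesis for these probes, without a test against the spread between plants. The choice of the set also favoured high values in Lasseter at 48 hours.

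At 12 hours fewer probes reached 1.8-fold, and more probes had a value: 695 in FLIP94-508C and 698 in ICC3996 lay far above the other 4 columns of these genotypes (584 to 615 and 584 to 617). Dilution of the share by extra probes was argued against by the 481 probes measured in all columns. Over these the 12-hour total was 5, against 12 to 22 at the other hours (mean 16.8). Its upper 95% Poisson bound was 11.7, which is too narrow where probes are correlated. Of the 5, ICC3996 gave 4, Lasseter 1 and the other genotypes 0. ICC3996 also had 4 at 6 hours and 5 or 6 later, so it shows little of the drop. A separate set of hybridisations at 12 hours cannot be told apart from the hour itself, because the lowest 12-hour column (674 measured probes) lies above every other column (highest 629). A weaker response at 12 hours stays open as an untested biological explanation.

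Probe CA0853 differed between ILWC245 and Lasseter, by 0.30 on the log2 scale. Chance could not be excluded for this count of 1 probe: 7 of 100 splits of the 10 columns into groups of 5 gave at least 1 probe, and the highest other split gave 2. These splits ignore the hours. With the columns exchanged within hours there are 16 arrangements, too few for a share under 0.05; the real one gave 1 probe and the highest other gave 1, with 2 of 16 giving as many. For the comparisons with a real count of 0 the regroupings carry no information on chance, since 100 of 100 must give at least 0; the highest other count was 1 for ICC3996 minus Lasseter, 1 for FLIP94-508C minus Lasseter, 1 for any difference among genotypes, 4 for any difference among hours and 1 for late minus early.

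Probe U461 stood at -0.32 in ICC3996 at 12 hours, where the other hours lay between -1.02 and -0.85. Probe LS0493 stood at 0.41 in Lasseter at 48 hours, against -0.40 to -0.25 at the other measured hours. Probe U222 stood at 0.93 in Lasseter at 48 hours, against 0.03 to 0.25 at the other hours.

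Among the control spots, which no comparison used, the normalisation control NORMCON3 reached an absolute log2 ratio of 0.75 in ICC3996 at 6 hours. Its SD was 0.33 over 20 columns, while NORMCON2 and NORMCON4 stayed within 0.12 and 0.20. NORMCON3 was above 0 in every genotype at 6 hours (0.02 to 0.75) and below 0 in every genotype at 24 hours (-0.48 to -0.29). In Lasseter at 48 hours it was -0.67. Whether this bears on the comparisons between hours or genotypes was not tested.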

How the results depend on the processing

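The exact tests by hour and genotype, the count of probes higher in all 4 genotypes and their settings were chosen after seeing the data. No named probe's estimate changed sign under any limma setting. The calls in Lasseter went from 6 higher and 7 lower to 6 higher and 4 lower after centring. Where a value moved, the cause was not tested unless named. Counts for ICC3996 and FLIP94-508C minus Lasseter and for any difference among genotypes stayed at 0 in every limma setting, with any of the 20 columns or any hour left out too.

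Mean-response counts (8 in FLIP94-508C, 7 in ICC3996, 1 in ILWC245, 13 in Lasseter) moved as follows. Quantile normalization gave 5 in FLIP94-508C and 0 in ILWC245. Without the hour term, whose variation then enters the spread, there were 1 in FLIP94-508C and 4 in ICC3996. Among probes complete in all columns, 0 passed in ILWC245, where U133 is not complete, and 27 in Lasseter; late minus early had 1. The methods' t-test without adjustment called 47 in FLIP94-508C, 67 in ICC3996, 48 in ILWC245 and 89 in Lasseter, and with adjustment 2, 1, 0 and 0; after the size filter it called 0 in each. For FLIP94-508C, ICC3996 and ILWC245 minus Lasseter it called 20, 55 and 74 without adjustment and 0 in ILWC245 with it. Robust eBayes gave 0 for ILWC245 minus Lasseter.

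Leaving out single columns or hours moved the mean-response counts to between 1 and 21 in FLIP94-508C, 2 and 11 in ICC3996, 0 and 5 in ILWC245 and 0 and 26 in Lasseter. Without the genotype's own column there were 1 (6 hours), 2 (24), 3 (48) and 21 (72) in FLIP94-508C, 4 (12 hours), 3 (24) and 2 (48, 72) in ICC3996, 0 (6 and 24 hours) and 5 (48) in ILWC245, and 0 (6, 48 and 72 hours), 3 (12) and 5 (24) in Lasseter. Columns of other genotypes moved some counts too. ICC3996 had 11 without ILWC245 at 48 hours, and Lasseter had 26 without FLIP94-508C at 24 hours. An unmoved count did not always hold the same probes. FLIP94-508C had 8 calls without its own 12-hour column, of which 4 were among its 8 main calls. It also had 8 without ICC3996 at 6 hours, and all 8 were main calls. With an hour left out in all genotypes (6, 12, 24, 48 and 72 in turn) there were 1, 15, 3, 2 and 17 in FLIP94-508C, 4, 8, 3, 3 and 2 in ICC3996, 0, 0, 0, 2 and 2 in ILWC245 and 0, 9, 8, 0 and 0 in Lasseter. ILWC245 minus Lasseter kept 1 without FLIP94-508C at 6, 12, 24 or 48 hours and had 0 without any other column or hour. Any difference among hours ran from 0 to 8 (8 without FLIP94-508C at 24 hours, 1 without FLIP94-508C at 12 hours or ILWC245 at 72 hours). Late minus early ran from 0 to 5 (5 without all 24-hour columns, 4 and 2 without FLIP94-508C at 24 and 48 hours, 1 without Lasseter at 24 or 72 hours or all 48-hour columns).

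At 1.5-fold, probes in any hour numbered 114 in FLIP94-508C, 111 in ICC3996, 90 in ILWC245 and 110 in Lasseter, with 572 values over all columns. At 2-fold they numbered 23 in FLIP94-508C, 39 in ICC3996, 15 in ILWC245 and 26 in Lasseter, with 115 values, and the exact p by genotype was 0.0467. In at least 2 hours there were 3 in FLIP94-508C, 9 in ICC3996, 2 in ILWC245 and 5 in Lasseter, and 0 probes higher in all 4 genotypes. Quantile normalization gave 34 in ICC3996 and 40 in each other genotype, which turns their order, and its exact p by hour of 0.00352 says nothing of the counts, which it makes nearly equal (8 or 9 per column). With an hour left out the counts ran from 26 (48 hours) to 41 in FLIP94-508C, 40 to 49 in ICC3996, 20 to 29 in ILWC245 and 26 (24 hours) to 40 in Lasseter, and 0 (24 hours) to 6 in all 4. The exact p by hour ran from 0.00146 (without ILWC245) to 0.0639 (without FLIP94-508C).

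Of 80 counts of single columns at 1.5-fold, at 2-fold, after centring and after quantile normalization, 45 moved by over 1.5 times. Another fold size and quantile normalization change these counts by construction. Centring gave 194 values at 1.8-fold over all columns, against 193. Of the values of named probes in the limma settings, 524 kept their side of the threshold, 97 lost it and 13 gained it. No values per replicate, no signal over background and no probe names were analysed here, so the gene lists and the averaging of probes of one name were not run.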

Other observations

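The tests in this part were chosen after the data had been seen. Columns of different genotypes at the same hour resembled each other more than columns that shared neither: the mean correlation across probes was 0.233 over 30 pairs of the same hour and 0.162 over 120 pairs that shared neither (permutation of hours within genotype, p = 0.00838, adjusted p = 0.0168 over 2 tests). Columns of the same genotype at different hours had a mean of 0.179 over 40 pairs (permutation of genotypes within hour, p = 0.208). Probes are not independent replicates, and the hour is confounded with any set of hybridisations.

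Probes whose IDs begin with LS made up 152 of the 711 measured probes and 5 of the 6 that were higher in every genotype. They reached 1.8-fold higher in some column more often than the rest (23 probes, odds ratio 2.84, 95% interval 1.53 to 5.17, Fisher's exact test, adjusted p = 0.00155 over 3 tests), and no such excess was seen among lower probes (odds ratio 0.892, 95% interval 0.420 to 1.76, adjusted p = 0.870). What the prefix stands for is not given in the sources used here. Of the probes with IDs beginning with LC, 41 of 41 had no value in any column.

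A later response of Lasseter, a hypothesis from the 6 common probes, may extend to other probes. With the 6 left out, the Lasseter 48-hour column correlated with the 24-hour columns of the other genotypes by 0.347 on average and with their 48-hour columns by 0.326. The difference of 0.0212 ± 0.0649 (SD over n = 3 genotypes) was above 0 for 1 of 3 genotypes, and the like difference was -0.139 ± 0.152 for the 48-hour column of FLIP94-508C (above 0 for 0 of 3), -0.0835 ± 0.0384 for that of ICC3996 (0 of 3) and -0.0463 ± 0.174 for that of ILWC245 (2 of 3). The difference for Lasseter lies within its spread, so a later response of the other probes is neither shown nor excluded.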
